A study of Mus musculus with 2 samples.

How the data were processed

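Total RNA from 1 mouse embryonic stem (ES) cell line carrying a 1.3 Mb deletion of the Williams-Beuren syndrome (WBS) region was measured on 2 Affymetrix expression arrays. Williams-Beuren syndrome is a human disorder caused by loss of a chromosome segment whose genes are largely shared with the mouse. The labels call the arrays biological replicates of 1 group and do not say whether they came from separate cultures or days, so the spread between them may be partly technical. Per the labels' protocols, the cells were kept with leukaemia inhibitory factor (LIF) and 20% serum replacement on a monolayer of feeder cells, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of total RNA. No sample without the deletion was analysed here, and the files hold no comparison between genotypes.

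The deposited values are log2 expression values, 1 per probe set and array, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA subtracts a modelled background, quantile-normalizes probe intensities over the arrays processed together and summarises the probes of each probe set. Its version, and which arrays were processed together, are not given in the sources used here. Quantile normalization makes the arrays' distributions nearly equal, so a change shared by most genes would not be seen. RMA gives no detection call, and probes differ in affinity, so the level of one gene was not set against that of another. Arrays have no read depth, and their number limits the precision. Every SD given here rests on 2 values. Columns that were not used numbered 0.

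Probe sets were named through a platform annotation table, and a check of symbols against the reference by gene identifier changed 0 of them. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and were left unnamed, and 9211 had none here. Identifiers of 34754 of those with 1 symbol matched the mouse reference gene table. For a gene with several probe sets, the one with the highest mean over both arrays stood for the gene, which gave 18194 genes.

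A gene was called above background when its mean over both arrays, and its value on each array, lay above the 95th percentile of 39 olfactory receptor genes, which served as probes without an expected transcript in ES cells. The threshold was 5.59 for the mean, with a 95% bootstrap interval from 5.00 to 5.68 over 10000 draws of these genes. By construction about 1 silent gene in 20 passes: on simulated values for the 39 reference genes, 7.00% of silent genes did. The reference genes had 1.13 probe sets each on average, against 1.92 for all genes and 2.19 for the listed genes. The choice of the highest probe set thus favours the other genes, and more of their silent members may pass. The median of all probe sets was an alternative.

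The replicates were compared by the difference of their log2 values (replicate 2 minus replicate 1) over the 12769 genes above the threshold on at least 1 array, with 1 log2 unit as the size of interest. For a gene list, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. These are descriptions of the 2 arrays, and no p-value is given, since genes are not replicates. On simulated differences for 12769 genes, the threshold of 1 log2 unit found 100 of 100 genes with a true difference of 1.5 log2 units, 1 of 100 with 0.75, and 0 of 12569 unchanged genes. Among the 12569 unchanged genes of the same simulation, 7 of 200 unshifted lists of 14 genes fell outside the central 95% of random lists. With a shift of 0.15 log2 units, 200 of 200 such lists lay above it. Shorter lists, whose random medians can spread more, were not simulated.

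The design, the background rule, 24 gene lists with 313 entries and the rule for named genes were fixed before the data were examined; 284 entries had a probe set of that 1 gene. The lists were the WBS segment, its flank, naive pluripotency, primed epiblast, the 2-cell-like state, endoderm, mesoderm, neuroectoderm, trophectoderm, feeder fibroblasts, blood cells, immediate early genes, LIF-STAT3, PI3K-AKT and TGF-beta signalling, the ATF4 and unfolded protein responses, heat shock, hypoxia and glycolysis, sterol synthesis, p53 targets, the cell cycle, imprinted genes, ribosomal proteins and oxidative phosphorylation. The rule named every measured gene of the WBS segment, the first 4 members above background and the first 2 that were not of each other list, in list order, and the 10 genes most above in each replicate, leaving out predicted genes without a name. Genes outside the rule are marked as chosen after their values were seen.

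The alternatives were loess of the difference against the mean (fraction 0.3), centring each array on its median, no filter on dim genes, the median of all probe sets of a gene, leaving out probe sets marked as shared between transcripts or genes (_a_at, _s_at and _x_at), a threshold of 1.5-fold, the 99th percentile of the olfactory receptors, 35 vomeronasal and taste receptor genes as the reference, each replicate alone, and every reference gene from Gtf2i to Fkbp6 as the segment. The bounds of the bootstrap interval and the fibroblast list without 3 broadly expressed members were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.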

Results

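The study profiled gene expression in a mouse ES cell line with a 1.3 Mb deletion of the WBS region, and its design text states that the aim was to find genes whose expression is altered in WBS. The data are 2 arrays of 1 group, with 45101 probe sets each. The median value was 6.01 on replicate 1 and 6.01 on replicate 2, with quartiles of 4.53 and 8.19 on replicate 1 and 4.51 and 8.21 on replicate 2. Of 18194 genes, 12437 (68.4%) were above background. Without a control line on these arrays, altered genes were not derived, and what follows describes which gene groups were measured above background and how closely the replicates matched. All 23 measured fibroblast markers were above background on the same arrays, so the counts of every list describe the whole RNA of the culture. Which cells a transcript came from was not resolved. Values are RMA log2 values, as mean ± SD (n = 2).

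Transcripts of 18 of the 22 measured genes of the WBS segment were above background. The segment lies on mouse chromosome 5 and runs from Gtf2i to Fkbp6 in the reference gene table; the labels do not say which of its genes lie within the deletion, nor how many copies were lost. Gtf2i, which encodes the transcription factor TFII-I, was at 9.996 ± 0.0039 on probe set 1425628_a_at. Its neighbour Gtf2ird1, which encodes a related factor, was at 8.87 ± 0.051 on 1451899_a_at. Baz1b, which encodes a chromatin-bound kinase, was at 9.82 ± 0.022 on 1434824_at, and Eif4h, a translation initiation factor, was at 12.35 ± 0.027 on 1438554_x_at. Rfc2, a subunit of the clamp loader of DNA replication, was at 9.53 ± 0.051, Limk1, a kinase of the actin cytoskeleton, at 7.38 ± 0.19, and Eln, which encodes elastin, at 7.998 ± 0.21.

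Further along the segment, Mettl27 was at 7.43 ± 0.12, Abhd11 at 9.42 ± 0.026, the syntaxin gene Stx1a at 8.31 ± 0.0070, Bud23, a methyltransferase for ribosomal RNA, at 9.36 ± 0.073, and Dnajc30 at 9.14 ± 0.044. Tbl2 was at 7.29 ± 0.11, Bcl7b at 8.02 ± 0.027, and Vps37d at 6.48 ± 0.033. The claudin genes of tight junctions were at 6.49 ± 0.10 for Cldn3 and 5.97 ± 0.17 for Cldn4, and Fzd9, a Wnt receptor gene, was at 6.26 ± 0.080. The 4 genes not above background were Clip2 (5.36 ± 0.021), Lat2 (4.64 ± 0.18), Tmem270 (5.60 ± 0.053) and Mlxipl (5.08 ± 0.054). Tmem270 exceeded the threshold on replicate 1 only. No probe set was assigned here to Fkbp6 alone.

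The largest difference between replicates among the segment genes above background was 0.30 log2 units, for Eln. The count rests on the brightest probe set of each gene: of 49 probe sets for these 22 genes, 36 were above background, and in Baz1b, Cldn3, Eif4h and Gtf2i some probe sets were and others were not. For Gtf2i the probe sets had means of 9.996, 7.67, 5.02 and 4.82. The median of all probe sets gave lower levels, 5.58 in place of 9.82 for Baz1b and 7.17 in place of 9.53 for Rfc2. All 23 measured fibroblast markers were above background on the same arrays, so the segment values come from RNA that also held fibroblast transcripts.

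**Figure D1:**
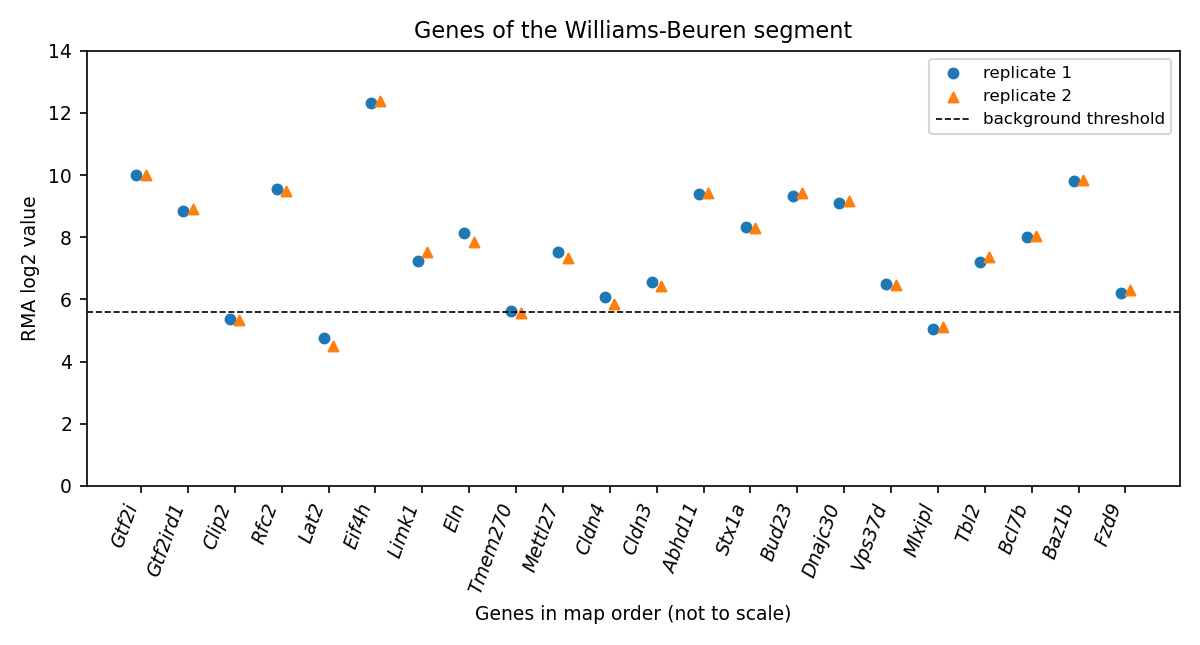
RMA log2 value (vertical axis) of each measured gene of the WBS segment, in map order along mouse chromosome 5 (horizontal axis, not to scale), with a point for each of the 2 replicates and a dashed line at the background threshold of 5.59. Points of a gene lie within 0.30 log2 units of each other, and Clip2, Lat2, Tmem270 and Mlxipl are the 4 genes not above background; values of different genes come from different probes and have no order.

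Beside the segment, 7 of 8 measured genes of the flank were above background. Gtf2ird2, another gene of the TFII-I family, was at 7.51 ± 0.11, Nsun5 at 8.34 ± 0.044, the nucleoporin gene Pom121 at 9.94 ± 0.034 and Hip1 at 7.12 ± 0.14. Ncf1, which encodes a subunit of the phagocyte NADPH oxidase, was not (4.29 ± 0.048).

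All 25 genes of the naive pluripotency list were above background, and 24 with the median of all probe sets. The core transcription factors of ES cells were at 12.63 ± 0.020 for Pou5f1, 12.11 ± 0.063 for Nanog, 12.11 ± 0.047 for Sox2 and 11.23 ± 0.044 for Klf4. Of genes typical of the later, post-implantation epiblast, 7 of 8 were above background: Otx2 was at 6.84 ± 0.12, Pou3f1 at 7.98 ± 0.069, the DNA methyltransferase gene Dnmt3b at 11.04 ± 0.034 and Lef1 at 7.66 ± 0.040. Fgf5, at 5.74 ± 0.27, passed the threshold on only 1 of the arrays. In the 2-cell-like list, Zfp352 (7.37 ± 0.0075) and Usp17la (9.19 ± 0.022) were above background and Tcstv1 (5.16 ± 0.59) and Tcstv3 (4.56 ± 0.061) were not; these belong to multigene families whose probes can bind several copies.

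Genes of the germ layers and of trophoblast gave a mixed picture. With fibroblast transcripts in the same RNA, the counts do not show that ES cells expressed these genes. In the endoderm list 10 of 12 were above background, among them Gata6 (7.72 ± 0.013), while Sox17 (5.81 ± 0.043), Foxa2 (5.72 ± 0.029) and Sox7 (5.90 ± 0.22) lay close to the threshold, and Gata4 (5.45 ± 0.050) and Afp (4.98 ± 0.11) were not above it. In the mesoderm list 4 of 9 were: Eomes at 7.99 ± 0.092, Mesp1 at 5.93 ± 0.024, the receptor gene Kdr at 6.67 ± 0.11 and Evx1 at 6.30 ± 0.12, whereas Mixl1 (5.08 ± 0.023) and Tbx6 (4.15 ± 0.14) were not. In the neuroectoderm list 4 of 8 were: Nes at 9.56 ± 0.045, Map2 at 8.79 ± 0.084, Zic1 at 9.92 ± 0.011 and Tubb3 at 8.20 ± 0.014, whereas the neural regulators Sox1 (5.23 ± 0.19) and Pax6 (5.54 ± 0.062) were not. In the trophectoderm list only Cdx2, at 5.74 ± 0.13, was above background among 7 genes; Elf5 (4.24 ± 0.14) and Gata3 (5.18 ± 0.18) were not. These counts moved with the threshold. At the lower bound of its bootstrap interval the trophectoderm count was 5 of 7. The endoderm count was then 11 of 12, the mesoderm count 6 of 9 and the neuroectoderm count 6 of 8. Sox1 and Pax6 passed at that bound, so their absence is not shown.

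All 23 measured markers of fibroblasts, the usual cell of feeder layers, were above background. The fibrillar collagen genes were at 12.67 ± 0.021 for Col1a1, 14.87 ± 0.0061 for Col1a2 and 14.86 ± 0.0025 for Col3a1, and the surface marker Thy1 was at 10.78 ± 0.019. The lowest of the 23 was at 8.81, over 3 log2 units above the threshold, and none of them differed by more than 0.10 log2 units between the replicates. None of the 23 was in another list. Some are also expressed outside fibroblasts. Without Vim, Fn1 and Sparc, an alternative added after seeing the data, 20 of 20 were above background. That outcome was fixed, since all 23 were above background, so it does not settle which cells the transcripts came from. Of the blood cell markers 3 of 6 were above background, Cd3e at 6.56 ± 0.023, Lyz2 at 9.33 ± 0.010 and Csf1r at 6.73 ± 0.19, whereas Ptprc, which encodes the pan-leukocyte antigen CD45, was at 4.05 ± 0.13 and Itgam at 3.92 ± 0.077.

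**Figure D2:**
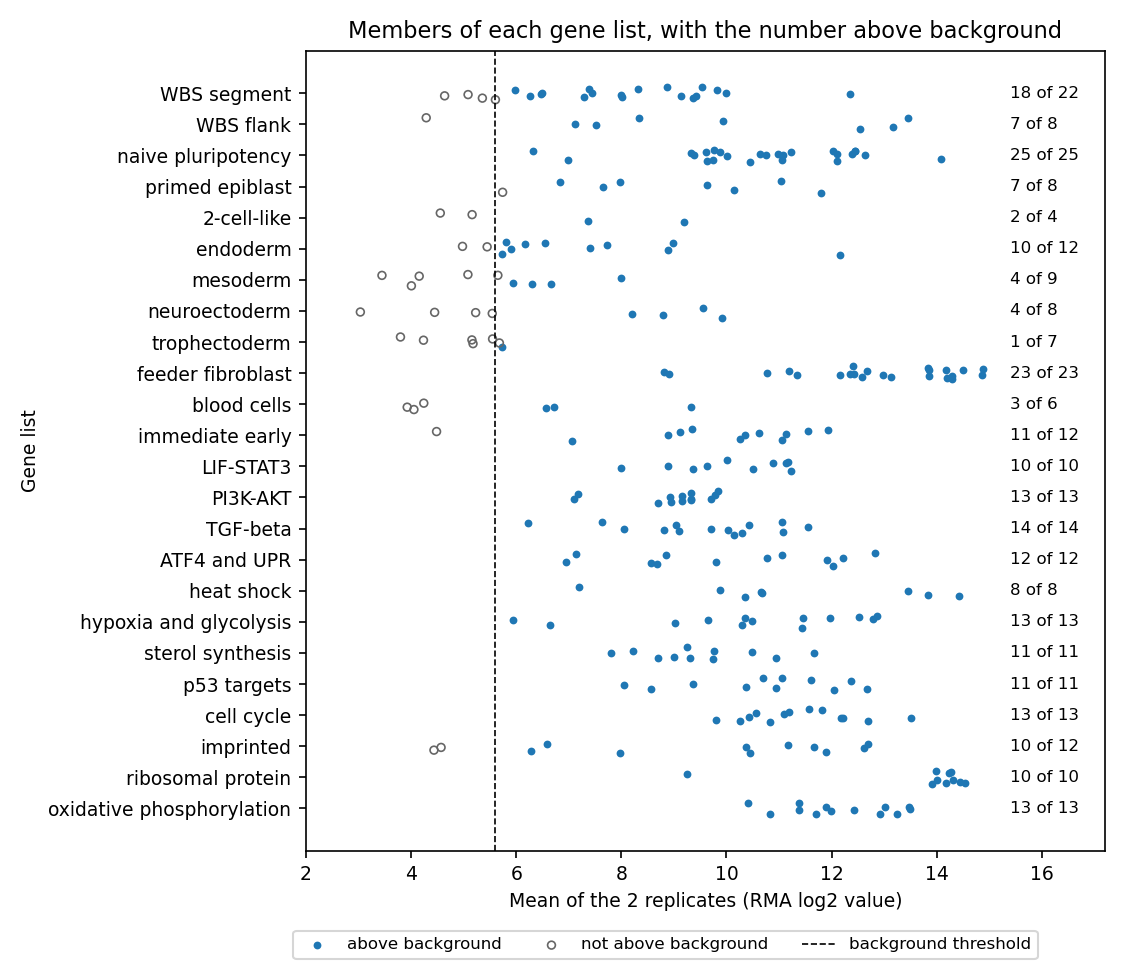
Mean RMA log2 value over the 2 replicates (horizontal axis) for every measured member of the 24 gene lists (vertical axis), with filled points above background, open points not above background, and the number above background at the right. All 25 naive pluripotency genes and all 23 fibroblast markers were above background, against 1 of 7 trophectoderm genes. The dashed line is the threshold of 5.59 for the mean. An open point can lie right of it when the gene did not pass on each array alone. The trophectoderm gene Krt7 (mean 5.68), chosen after its values were seen, is such a case. Levels of different genes come from different probes and have no order.

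Signalling genes were largely above background. All 10 genes of LIF-STAT3 signalling, which keeps mouse ES cells undifferentiated, were, including the receptor subunit genes Lifr (9.62 ± 0.0047) and Il6st (11.14 ± 0.032), Stat3 (10.51 ± 0.022) and its feedback inhibitor Socs3 (10.89 ± 0.099); with the median of all probe sets 9 were. All 13 measured PI3K-AKT genes were, with the catalytic subunit genes Pik3ca at 8.69 ± 0.11 and Pik3cb at 7.17 ± 0.11, the regulatory subunit gene Pik3r1 at 8.94 ± 0.19 and Akt1 at 9.71 ± 0.10. All 14 TGF-beta genes were, with Tgfb1 at 6.22 ± 0.091, the receptor genes Tgfbr1 at 10.30 ± 0.040 and Tgfbr2 at 11.05 ± 0.035, and Smad2 at 9.04 ± 0.040; with the median of all probe sets 12 were, and with unshared probe sets 12 of 13. Of the immediate early genes, which respond to growth factors and handling within minutes, 11 of 12 were, with Fos at 9.34 ± 0.090, Egr1 at 11.56 ± 0.023, Egr2 at 9.11 ± 0.0092 and Ier2 at 11.13 ± 0.026; Fosb was not (4.48 ± 0.060).

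The stress and metabolic lists were above background in every measured member on the brightest probe set of each gene. These were 12 of 12 genes of the ATF4 and unfolded protein responses (Atf4 11.91 ± 0.055, Ddit3 8.69 ± 0.046, Trib3 7.14 ± 0.11, Asns 12.04 ± 0.013), 8 of 8 heat shock genes (Hspa1a 7.20 ± 0.088, Hspa1b 10.35 ± 0.12, Dnajb1 10.65 ± 0.0086, Hsph1 10.68 ± 0.061) and 11 of 11 p53 targets (Cdkn1a 12.37 ± 0.024, Mdm2 10.38 ± 0.012, Ccng1 12.67 ± 0.0076, Trp53inp1 12.05 ± 0.0028), or 10 of 11 with unshared probe sets. Hspa1a and Hspa1b are near-identical copies, so their probes may not tell them apart. In hypoxia and glycolysis 13 of 13 were (Vegfa 9.03 ± 0.019, Slc2a1 11.46 ± 0.034, Bnip3 9.64 ± 0.00045, Ldha 12.52 ± 0.042), and in sterol synthesis 11 of 11 (Hmgcs1 11.67 ± 0.023, Sqle 9.77 ± 0.014, Idi1 9.75 ± 0.0021, Insig1 9.004 ± 0.060). So were 13 of 13 cell cycle genes (Mki67 10.56 ± 0.028, Top2a 11.82 ± 0.022, Cdk1 11.56 ± 0.025, Ccna2 10.82 ± 0.033), 10 of 10 ribosomal protein genes (Rpl4 14.28 ± 0.015, Rpl7 14.01 ± 0.020, Rpl8 13.91 ± 0.0070, Rpl10a 14.24 ± 0.0073) and 13 of 13 respiratory chain genes (Ndufa4 12.42 ± 0.020, Ndufb8 11.98 ± 0.036, Ndufs1 10.41 ± 0.019, Ndufv1 11.38 ± 0.0013).

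Of the imprinted genes, which are expressed from 1 parental copy, 10 of 12 were above background, with Igf2 at 12.69 ± 0.027, its receptor gene Igf2r at 11.17 ± 0.046, Peg3 at 10.45 ± 0.010 and Mest at 10.37 ± 0.013. Zim1 (4.43 ± 0.023) and Peg10 (4.57 ± 0.26) were not.

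The replicates differed little. Over the 12769 genes above the threshold on at least 1 array, the SD of the difference was 0.114 log2 units, which corresponds to an error of 0.0807 for 1 array, and 95% of genes differed by between -0.24 and 0.24. No gene differed by 1 log2 unit or more, and 10 differed by at least 1.5-fold, 6 higher in replicate 2 and 4 higher in replicate 1. Among all 45101 probe sets, 2 without a gene name here passed 1 log2 unit, with differences of -1.33 and -1.02 at values of 5.89 and 5.70 on replicate 1. Of the 10 genes past 1.5-fold, 9 had a mean less than 1 log2 unit above the threshold or below it. Across genes, which are not independent replicates, Pearson's r was 0.998 and Spearman's rho was 0.998. The SD was 0.167 in the dimmest genes, with means up to 4.09, and 0.191 in those with means between 4.09 and 4.82, above which it fell with level to 0.0556 in those above 10.68.

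The 10 genes most above in replicate 1 were Fbp1, Ms4a10, Npas4, Kcnh1, Zfp956, Cpn1, Ptger1, Iba57, Tacr1 and Frs3os, by 0.56 to 0.70 log2 units, all with means between 5.30 and 6.49. The 10 most above in replicate 2, by 0.51 to 0.96 log2 units, were Rufy2, Tm6sf1, Malat1, Plch1, Ly6d, Acss1, Nts, Slc16a12, Ksr2 and Capsl. Malat1, a nuclear long non-coding RNA, differed by 0.74 log2 units at a mean of 11.53, a level at which the SD over genes was 0.0556. That value is of 1418189_s_at, a probe set marked as shared; the bright unshared Malat1 probe sets 1429060_at and 1436202_at differed by 0.0086 and -0.0011. The other 9 genes had means between 5.35 and 6.78.

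**Figure D3:**
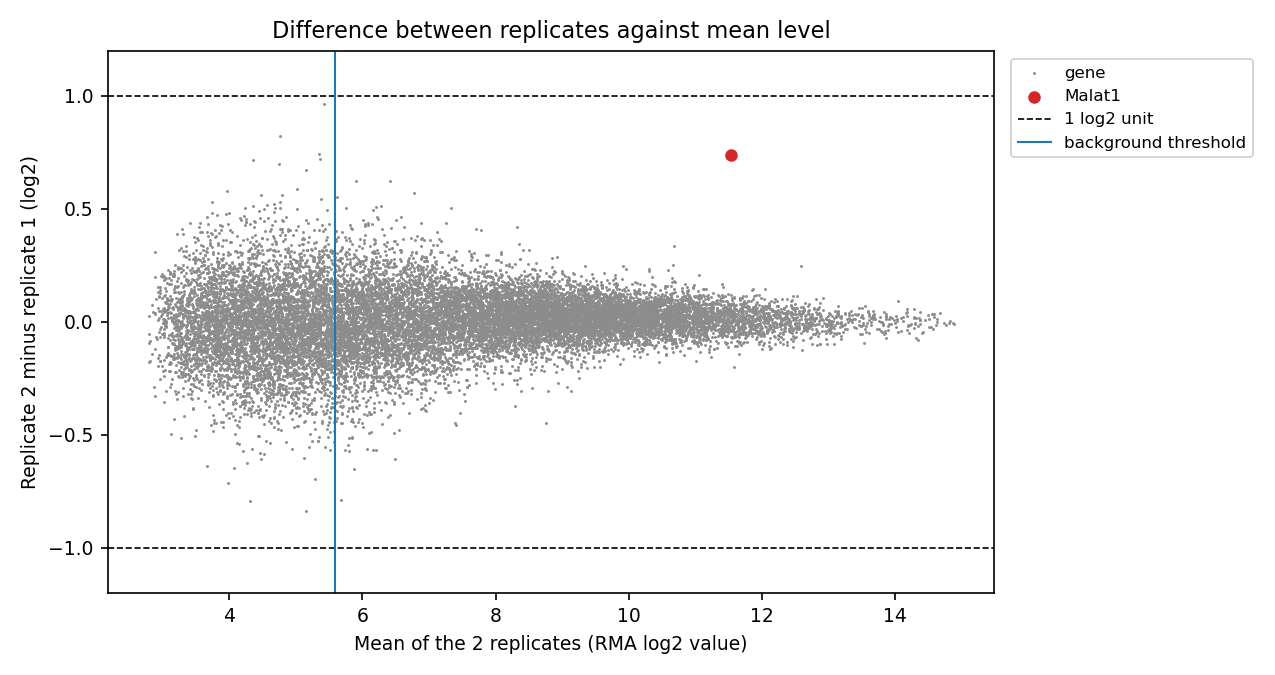
Difference between the replicates (replicate 2 minus replicate 1, log2, vertical axis) against their mean RMA log2 value (horizontal axis) for 18194 genes, with dashed lines at 1 log2 unit and a vertical line at the background threshold. All points lie inside the dashed lines, the spread narrows with level above a mean of 4.82, and Malat1 (red), here on a shared probe set, stands at a difference of 0.74.

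The medians of the 24 lists differed between replicates by between -0.13 (mesoderm) and 0.048 (WBS flank) log2 units. The mesoderm median rests on 5 members and was inside the central 95% of random lists (-0.16 to 0.15), at percentile 4.99. The heat shock list was the 1 list outside the central 95% of random lists, with a median of -0.043 at percentile 1.22, where chance alone would place 1.2 of 24; it was inside after loess of the difference against the mean and with unshared probe sets alone, which left 0 lists outside, and with the median of all probe sets, which placed the hypoxia and glycolysis list outside instead. The WBS segment (median 0.031, percentile 71.5), naive pluripotency (0.018, percentile 64.1) and fibroblast lists (-0.0070, percentile 15.98) were inside.

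The 3′ value minus the 5′ value, a sign of RNA integrity, was 0.27 on replicate 1 and 0.26 on replicate 2 for Actb, and -0.060 and -0.10 for Gapdh. The 18 hybridisation control probe sets, for bacterial and phage transcripts added in fixed amounts, differed by a median of 0.050 log2 units, from -0.0042 to 0.22, and 17 of them were higher in replicate 2. The 24 control probe sets for Bacillus transcripts differed by a median of 0.025 log2 units, from -0.19 to 0.27, and 14 of them were higher in replicate 2.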

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

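Of 217 alternative values for the main results, 209 stayed within 1.5 times the reported value and 8 did not. These are counts and SDs, which have no direction, and centring each array cannot change the SD of the difference. The count of genes above background was 12437 and ranged from 12109 at the upper bound of the bootstrap interval to 13900 at its lower bound, and each array alone gave 12600 to 12606. With unshared probe sets alone, 11522 of the 16593 genes still measured were above background. For the WBS segment the count of 18 of 22 became 20 of 22 with the median of all probe sets, each gene then being set against a threshold made the same way, 17 of 18 with unshared probe sets, 20 of 27 with every reference gene from Gtf2i to Fkbp6, 21 of 22 at the lower bound, and 18 to 19 with each array alone. The trophectoderm count of 1 became 2 with the vomeronasal and taste receptors, 2 with the median of all probe sets and 5 at the lower bound, and 1 to 2 with each array alone; the first 3 of these settings lower the threshold or change the probe set. Of the lists wholly above background, naive pluripotency fell to 24 of 25, LIF-STAT3 to 9 of 10 and TGF-beta to 12 of 14 with the median of all probe sets, and TGF-beta to 12 of 13 and p53 targets to 10 of 11 with unshared probe sets. The mesoderm and neuroectoderm counts of 4 each became 6 at the lower bound, which is 1.5 times the reported value. The ribosomal protein count fell from 10 of 10 to 5 of 5 because 5 of its 10 genes had only shared probe sets. The SD of the difference between replicates, 0.114, was 0.136 without the filter on dim genes, and 0 genes passed 1 log2 unit under any normalization, filter or probe set rule, against 10 at 1.5-fold. The 1 list outside the central 95% of random lists became 0 with loess and 0 with unshared probe sets; with the median of all probe sets it was hypoxia and glycolysis, and the heat shock median moved from -0.043 to -0.013. Heat shock was outside again only with all measured members, which left its 8 members as they were, and the cause was not tested. With the median of all probe sets, 10 of the 11 segment genes that have several moved by more than their SD between replicates; the level fell by 0.17 to 4.24 log2 units over the 11. Using 1 array alone cannot move a mean of 2 by more than its SD. Of the list medians, 14 of 96 moved by more than the SD of random lists. No paired analysis was possible because both arrays belong to 1 group. Genes near the threshold are limited by their signal over background: silent and weakly expressed genes cannot be separated there.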

Other observations

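The tests of the whole transcript and of nuclear-retained RNA, and those on the fibroblast markers, were chosen after their results were seen; those of brightness and of paired probe sets were written before.

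Transcripts of marker genes of both sex chromosomes were above background on these arrays; which cells of the culture they came from was not resolved. The genes of this paragraph were chosen after seeing the data. Xist, the RNA that coats the inactive X chromosome, was at 11.96 ± 0.027 (SD, n = 2). Among Y-linked genes, Eif2s3y was at 9.22 ± 0.042, Kdm5d at 6.01 ± 0.32 and Uty at 6.05 ± 0.020. The maternally expressed RNAs of the imprinted Dlk1-Dio3 locus were also above background, with Meg3 at 12.62 ± 0.027, Rian at 8.61 ± 0.14 and Mirg at 8.66 ± 0.037. So was the paternally expressed Dlk1 at 6.27 ± 0.088. The probe sets of Xist, Meg3 and Dlk1 are marked as shared. Kdm5d and Uty lay close to the threshold of 5.59.

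Fibroblast transcripts stood beside those of pluripotency on both arrays, with 100% of the 23 measured fibroblast markers above background. RNA of the feeder layer, on which the labels say the cells were always grown, is a candidate source; that share is the pattern itself, so it gives this source no further support. The collagen genes Col1a2 and Col3a1 were at 14.87 and 14.86. Mesoderm-like cells that arose in the culture could add such transcripts too. Of the measured mesoderm regulators, 44.4% were above background. Only all or none of them would have counted as an answer, so nearly any share would have decided neither way. The sources cannot be told apart. No step that removes feeder cells before extraction is named in the labels. If feeder RNA was present, the values of the WBS segment would hold transcripts of cells that need not carry the deletion, which these arrays cannot separate.

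Of 12168 probe sets with a mean above 8, 6 differed by 0.5 log2 units or more between the replicates, and 5 of them belonged to Malat1 (3) and Atrx (2), the latter gene chosen after its values were seen. All 5 were higher in replicate 2; the 3 of Malat1 are marked as shared and the 2 of Atrx are not, so with the brightest unshared probe set the Malat1 difference was 0.0086, though the dimmer unshared 1452378_at differed by 0.42, as 1420946_at of Atrx did by 0.40. A change of the whole transcript is argued against, since not all bright probe sets of the same genes moved: 1436202_at of Malat1 differed by -0.0011 and 1453734_at of Atrx by 0.022, against SDs of 0.074 and 0.092 among equally bright probe sets. Unequal recovery of nuclear-retained RNA is argued against by 8 other such RNAs, whose median difference was -0.0078 (range -0.20 to 0.20). For brightness-dependent normalization, the smallest of the 5 differences after loess was still 7.615 SDs. The 5 were picked for large differences among bright probe sets, so that outcome was largely fixed by the selection and decides nothing. An effect on part of these transcripts or on their labelling, or for Malat1 on other RNA bound by its shared probe sets, may remain, and no probe sequences were used to test it; no biological explanation was tested, since both arrays belong to 1 group.

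If the small differences between the replicates were real differences of genes, separate probe sets of a gene would move together. Across 1089 genes with 2 bright unshared probe sets, the rho of their differences was 0.058 after loess. It lay between the lowest (-0.096) and highest (0.11) of 1000 shuffled pairings. That full range is a wide bar, so the test cannot tell a weak positive correlation from array noise alone. The covariance of the pairs gave a shared SD of 0.015 log2 units, against SDs of 0.070 and 0.094 for the 2 probe sets. For these genes, little of the spread was thus shared. A shared component too small for this test may still exist, and the test does not say whether the RNA came from separate cultures.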
